A study of Arabidopsis thaliana with 12 samples.

How the data were processed

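Transcript levels were measured in whole seedlings of the Arabidopsis thaliana line Col:LUC on Affymetrix ATH1 arrays, which read each transcript through sets of short probes at 3' ends. Per the labels' protocols, seedlings grew on B5 medium for 10 days, then for 3 days on B5 with or without 4.5 µM NAA, and were treated with 50 µM antimycin A for 3 hours, in biological triplicate. Labelled RNA was made from 400 ng of total RNA with biotin, also per the labels. Whether untreated seedlings received the solvent of antimycin A is not given in the sources used here.

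The authors deposited 1 table of linear intensity values, with a row per probe set and a column per array, and 12 of 12 columns were matched to a sample by its own label. The submitters' processing notes name MAS5, RMA and Partek, with no role, order or version, and which of these made the deposited values is not given in the sources used here. No header or label records a normalization between arrays, but the deposited values carry its marks. Their outer quartiles were nearly equal (25th percentiles of 6.38 to 7.16 and 75th percentiles of 164.1 to 174.1), and 4 of the 12 arrays shared a maximum of 34744.57. Their medians differed more, at 33.72 to 36.2 on B5 and 38.81 to 39.73 on NAA. Since the deposited intensity values were linear where log2 values had been assumed before the data were examined, the fallback fixed at that time was used, log2(value + 16), and fold changes are on this scale, which understates the change of dim transcripts. The lowest values lay between 2.11 and 2.58 and the table gives no detection call, so that no lower limit of detection was set. How any such normalization treated arrays whose total messenger content differs is unknown, and a change shared by most transcripts would not be seen.

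Of 22810 rows, 64 control probe sets were left out and 22746 were tested. A probe set took its gene from the annotation table given for the array, which pairs 13513 probe sets with 1 gene, 503 with several and leaves 8730 unnamed here. These gave 13355 genes, of which 11778 are printed by locus code. Current symbols were taken from the RefSeq table of assembly TAIR10.1, used for names only, and no coordinates are given. A gene with several probe sets was represented by the brightest over the 12 arrays. AOX1A, planned as a named gene, and its relatives are not analysed here.

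Groups and replicate numbers were taken from the sample titles. The linear model of limma was fitted to all 12 arrays with a mean for each of the 4 groups (8 residual degrees of freedom), with empirical Bayes moderation, 5 contrasts, two-sided moderated tests and Benjamini-Hochberg adjustment over all probe sets, called at an adjusted p below 0.05. The contrasts were the antimycin A effect on B5, the antimycin A effect on NAA, the NAA effect without and with antimycin A, and the difference of the antimycin A effects (on NAA minus on B5). Errors are SD of the deposited intensities within a group, or SE of the fitted log2 fold change. Camera tested gene lists against all other genes with a preset correlation of 0.01 and again with a correlation estimated per list, with adjustment over the lists of a contrast. The slope and the correlation of effects had jackknife SE over the arrays.

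Of 29 gene lists fixed before the data were examined, 12 had at least 5 measured members and were tested: mitochondrial retrograde response, alternative respiratory chain, Aux/IAA, GH3 and auxin inactivation, heat shock, respiratory chain, glutathione transferase, detoxification (glycosyltransferases, P450 enzymes and transporters), rapid stress, photosynthesis, expansin and XTH, and sugar starvation genes. HSP23.5, NDB2 and DTX3 stand in 2 lists each. For lists with 1 to 4 measured members the members' calls are given, and 4 lists with none (regulators of the retrograde response, mitochondrial import, ethylene, root tissue markers) are not analysed here. Many fixed members had no name in the annotation used, so a list's count describes its measured members alone (10 of 20 retrograde genes, 7 of 41 photosynthesis genes).

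The named genes follow a rule fixed before the data were examined: per contrast the 6 largest rises and 6 largest falls among called probe sets of 1 gene whose groups do not overlap (for the difference, among those called), and up to 3 measured members of each list by adjusted p, with NDB2 and UPOX in every contrast. No named gene had called probe sets of opposite sign. Further list members were added after their values were seen, as were 45 sets of genes made from symbol stems and the plastid and mitochondrial genomes, and the counts of smaller and larger rises and falls. Exact permutation tests compared mean scores of such sets by exchanging arrays within the levels of the other treatment (400 rearrangements, smallest p 0.005).

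Alternatives were quantile normalization, median centring, filters on dim probe sets, other variance models, array weights, separate fits of 6 arrays, a replicate block, a single probe set per gene, pseudocounts of 1 and 64, each array left out in turn, and camera on ranks or rotation tests (fry). On simulated data with the real spread, the fit for the antimycin A effect on B5 recovered 76 of 100 probe sets changed 2-fold. It recovered 99 of 100 changed 4-fold, with 12 false calls among the unchanged of 22746 probe sets. For the difference it recovered 53 and 98 of 100, with 15 false calls. Camera called 2 of 2 changed and 0 of 20 unchanged simulated sets of 10 genes. The changed probe sets were drawn from brighter ones only, so the recovery of dim ones is not known. Only 100 were changed at each fold, far fewer than the 7504 probe sets called in the real comparison on B5. The adjustment depends on that share, so neither the recovery nor the number of false calls carries over to the real data. Genes were simulated as independent, so these sets do not show how often camera calls unchanged lists of correlated genes. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 for figures.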

Results

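Gene expression was measured in seedlings of the Arabidopsis thaliana line Col:LUC, in the ecotype Col-0, on Affymetrix arrays, 1 array per sample. Seedlings grew for 10 days on B5 medium, a standard plant culture medium, and then for 3 days on fresh B5 plates with or without 4.5 µM NAA, a synthetic auxin. Part of the seedlings on each medium was then treated for 3 hours with 50 µM antimycin A, an inhibitor of complex III of the mitochondrial respiratory chain. The 4 groups (B5, B5 with antimycin A, NAA, NAA with antimycin A) hold 3 arrays each, in biological triplicate per the labels. The 12 arrays had median intensities between 33.7 and 39.7, and their number limits the precision. Arrays of the same group correlated at 0.99 or above over probe sets, and pairs from different groups at 0.91 to 0.98. The first principal component held 60% of the variance and separated arrays with from arrays without antimycin A, and the second held 24.7% and separated NAA from B5. Of the fixed reference genes, UBC21, TIP41 and SAND were measured, and none was called over all probe sets in any of the 5 comparisons (log2 fold changes of -0.23 to 0.27). Adjusted over the list alone TIP41 was called higher with NAA among seedlings with antimycin A (0.27), and in 3 of the 5 comparisons 1 of these genes had an unadjusted p below 0.05, while TIP41 and SAND passed the threshold in 1 or 2 alternative settings of the analysis. SAUR10, the measured gene of the SAUR list of auxin-induced genes, was not called in any comparison by limma, nor at an unadjusted p below 0.05 (log2 -0.03 to 0.08). It read 6.22 to 9.79 on the 12 arrays, below the pseudocount of 16, and stands for 1 of 33 fixed SAUR genes. Its values therefore say little about that list. The control probe set for 25S ribosomal RNA, a gauge of the labelled RNA rather than of a messenger, read 5380 ± 347 on B5, 8240 ± 175 on B5 with antimycin A, 6080 ± 477 on NAA and 12000 ± 317 on NAA with antimycin A (SD, n = 3).

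The first comparison asked how transcript levels changed with antimycin A in seedlings on B5 medium. Since solvent treatment of the untreated seedlings is not given, an effect of the solvent cannot be told apart from one of antimycin A. Antimycin A raised every measured member of the mitochondrial retrograde response list, genes of the nucleus known to respond to impaired mitochondria. UPOX, a mitochondrial protein induced by oxidative stress, went from an intensity of 73.2 ± 16.1 to 3830 ± 147 (SD, n = 3), a log2 fold change of 5.45 ± 0.19 (SE; adjusted p = 2.4e-07). AT2G41730 went from 85.7 ± 19.7 to 12100 ± 1000 (log2 6.91 ± 0.13, adjusted p = 1.26e-08), the highest rise of a named gene, on a probe set that may also read similar transcripts. NDB2, an external alternative NAD(P)H dehydrogenase of the inner mitochondrial membrane, rose from 113 ± 8.34 to 557 ± 140 (log2 2.12 ± 0.20, adjusted p = 5.08e-05). Of 7 photosynthesis genes 5 fell, a list whose camera call was lost with an estimated correlation (adjusted p = 0.216), and the 3 measured cell cycle genes, too few for a list test, fell too. LHCB4.2, an antenna protein of photosystem II, went from 7210 ± 406 to 2130 ± 582 (log2 -1.79 ± 0.19, adjusted p = 9.72e-05).

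All 10 measured retrograde genes rose on B5, over all probe sets as well as adjusted over the list alone, with a median log2 fold change of 5.38 (camera adjusted p = 1.13e-13, and adjusted p = 0.0162 with an estimated correlation). They included the MATE family efflux carrier DTX3 (6.35), the mitochondrial small heat shock protein HSP23.5 (5.31) and the locus AT2G32020 (5.57). Of the 6 measured heat shock genes 5 rose, and 6 when adjusted over the list alone (median 1.88, camera adjusted p = 1.53e-05, and adjusted p = 0.0268 with an estimated correlation). HSP26.5 rose from 7.71 ± 0.35 to 150 ± 12.8 and ROF2, a heat-induced peptidyl-prolyl isomerase, from 91.2 ± 1.55 to 306 ± 48.6. Of 6 detoxification genes 5 rose, and 5 adjusted over the list alone, among them the glycosyltransferases UGT73B4 (log2 4.29) and UGT73B5 (3.77), with a median of 3.58 (camera adjusted p = 1.26e-05, but adjusted p = 0.0914 with an estimated correlation). Of 5 rapid stress genes 4 rose, and 5 adjusted over the list alone, led by the calmodulin-like CML38 (2.76) and the transcription factors WRKY53 (2.16) and WRKY6 (1.72). The camera test of that list gave an adjusted p = 0.00107, and adjusted p = 0.216 with an estimated correlation. Of 7 photosynthesis genes 5 fell, and 7 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.000666, but adjusted p = 0.216 with an estimated correlation). PRK, phosphoribulokinase of the Calvin cycle, fell by 1.04 on the log2 scale.

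In the alternative respiratory chain list, NDB2 and NDB4 (log2 2.31) rose and the other 3 of 5 members were not called, with the same count adjusted over the list alone (camera adjusted p = 0.141). GH3 and auxin inactivation genes were divided. GH3.3, an enzyme that conjugates auxin to amino acids, rose from 16.4 ± 7.98 to 1280 ± 284 (log2 5.33 ± 0.20, adjusted p = 3.39e-07) without added auxin, GH3.5 and the auxin oxidase DAO1 rose by 1.59 and 1.13, and GH3.17 fell by 1.05. The list as a whole had 3 rises and 1 fall among 6 members, the same adjusted over the list alone, and was not called (camera adjusted p = 0.141). Among 8 glutathione transferases 2 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0823). GSTU25 rose from 212 ± 28.8 to 2830 ± 782, whereas GSTU20 fell from 9070 ± 727 to 2460 ± 543 and GSTU18 from 389 ± 74.4 to 79.2 ± 17.2. Of 9 expansin and XTH genes, which loosen or remodel cell walls, 4 rose and 4 fell, and as many adjusted over the list alone. XTH18 rose by 4.64 and XTH33 by 1.49, while EXPA15 fell by 2.53, and the list's median of 0.42 and mean of -0.07 differ in sign (camera adjusted p = 0.926).

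Respiratory chain genes on B5 had 1 rise and 2 falls among 10 members, and 1 rise and 0 falls adjusted over the list alone (camera adjusted p = 0.306). Cytochrome c CYTC-2 rose by 0.83, CYC1-2 fell by 0.47 and COX5B by 0.31, the last with its call lost in 13 of 25 alternative settings. Of 6 Aux/IAA genes IAA18 alone rose (0.57), also adjusted over the list alone (camera adjusted p = 0.206). Of 5 sugar starvation genes MCCA and D2HGDH fell (-0.55 and -0.58), and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.235). Some lists had too few members for a test. The 3 cell cycle genes all fell, with values of -1.22 for the Aurora kinase AUR2, -1.01 for the replication factor MCM7 and -0.70 for AUR1. Of 4 lateral root genes the polygalacturonase PGLR fell by 1.24 and the others were not called. Both root hair expansins fell, EXPA18 by 2.16 and EXPA7 by 1.06. Of the dehydration genes COR15A and COR47 fell (-2.74 and -0.71) and the dehydrin LTI30 rose (1.25). Of 3 hypoxia genes LDH, lactate dehydrogenase, rose by 3.74 and PDC2 by 0.79. GRX480, a glutaredoxin and the measured member of the salicylic acid list, rose by 2.95. BCAT4, an early enzyme of methionine-derived glucosinolate synthesis, fell by 2.16. The clock gene GI fell by 0.49, and the antioxidant enzymes GR2 and PRXIIF fell by 0.81 and 0.51. Of the stomatal lineage markers SPCH had a log2 fold change of 0.01 (SE 0.02), and FAMA fell by 0.40, a call lost in 15 of 25 alternative settings. SPCH read 5.16 to 6.16 on every array of the study, too dim for a fall to be seen.

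The largest rises on B5 also included the retrograde list member AT5G43450 (log2 5.6) and, outside the lists, AT3G09405 (5.54). The largest falls of named genes were those of AT5G11070 (-3.61), AT1G23390 and AT1G49500 (both -3.56), AT3G20820 (-3.54), AT5G60680 (-3.48) and AT1G52000 (-3.47). In all, limma called 7504 of 22746 probe sets (33%), 3257 higher and 4247 lower, at an adjusted p below 0.05. Of these 2392 changed at least 2-fold (1279 higher, 1113 lower), and 1144 of the 2392 had no gene name here. The 3 arrays with antimycin A did not overlap the 3 without for 60.7% of probe sets, where chance gives 10%. Under another grouping of the same 6 arrays camera called up to 6 lists, against 5 with the real groups. Every other grouping has treated and untreated arrays on both sides in unequal number, so part of the effect stays in it. Its list count is therefore not a chance level, and the same holds for such groupings in the comparisons below.

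**Figure D1:**
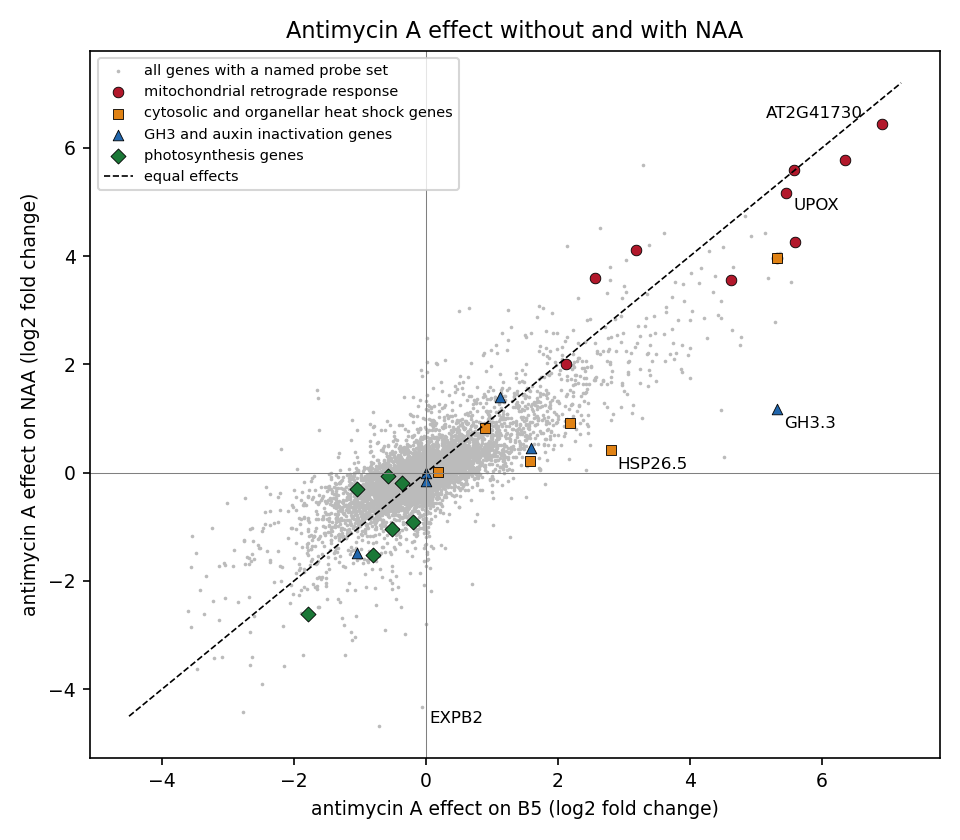
Log2 fold change with antimycin A on NAA medium (vertical axis) against that on B5 medium (horizontal axis) for 13355 genes (grey points, means of 3 arrays per group), with members of 4 fixed gene lists marked by colour and shape and the dashed line at equal effects. Retrograde genes lie high on both axes (UPOX at 5.45 and 5.16), while GH3.3 (5.33 and 1.17) and HSP26.5 (2.81 and 0.41) lie far below the line; HSP23.5, a member of both lists, is drawn as a heat shock gene.

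The second comparison asked the same question in seedlings that had spent 3 days on NAA. The retrograde genes again all rose: UPOX went from 52.4 ± 17.1 to 2400 ± 351 (SD, n = 3; log2 5.16 ± 0.19, adjusted p = 4.66e-07), NDB2 from 163 ± 42.4 to 692 ± 38.9 (2.01 ± 0.20, adjusted p = 0.000105) and AT2G41730 from 100 ± 11.1 to 10100 ± 247 (6.45). GSTU22 rose from 361 ± 94.6 to 3020 ± 122 (log2 3.04 ± 0.18, adjusted p = 4.21e-06) and the beta-glucosidase BGLU28 from 17.7 ± 9.18 to 1680 ± 35.7 (5.69). Of the sugar starvation list, IVD and MCCA, enzymes of leucine breakdown, rose as well, IVD from 64 ± 5.18 to 177 ± 16.5 (1.27 ± 0.07, adjusted p = 2.61e-06) and MCCA from 89.3 ± 15.9 to 176 ± 9.73 (0.88 ± 0.13, adjusted p = 0.00102). LHCB4.2 fell from 5400 ± 479 to 868 ± 118 (-2.62 ± 0.19, adjusted p = 1.58e-05), and the beta-expansin EXPB2 from 653 ± 193 to 17.0 ± 7.36 (-4.33).

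On NAA the 10 retrograde genes had a median log2 fold change of 4.19, and all 10 were called adjusted over the list alone (camera adjusted p = 3.08e-17, and adjusted p = 0.00764 with an estimated correlation). This was the only list whose call on NAA held with an estimated correlation. Of 6 detoxification genes 5 rose, and as many adjusted over the list alone (median 2.66, camera adjusted p = 7.5e-07, but adjusted p = 0.0689 with an estimated correlation). UGT73B4 rose by 4.1 and UGT73B5 by 3.52. Of 5 rapid stress genes 4 rose, and 4 adjusted over the list alone, with ZAT10 at 2.50 and WRKY53 at 2.05 (camera adjusted p = 0.000308, but adjusted p = 0.105 with an estimated correlation). Of 6 heat shock genes 4 rose, and 4 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.00398, but adjusted p = 0.0689 with an estimated correlation). HSP23.5 rose by 3.97 and HSP15.7 by 0.83. Of 7 photosynthesis genes 4 fell, and 4 adjusted over the list alone (median -0.92, camera adjusted p = 0.000155, but adjusted p = 0.12 with an estimated correlation), among them the photosystem I subunits PSAN (-1.52) and PSAE1 (-0.92). Of 5 sugar starvation genes 3 rose, and 3 adjusted over the list alone, namely IVD, MCCA and the SnRK1 kinase subunit AKINB1 (0.70), the last of which lost its call in 11 of 25 alternative settings. The list's camera adjusted p was 0.0148, and adjusted p = 0.0689 with an estimated correlation.

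Of the 6 Aux/IAA genes, early auxin response repressors, IAA30 rose by 1.68 and IAA29 by 1.15 on NAA, the same 2 adjusted over the list alone (camera adjusted p = 0.0148, but adjusted p = 0.0689 with an estimated correlation). The respiratory chain list was called lower (median -0.15, camera adjusted p = 0.0269, but adjusted p = 0.298 with an estimated correlation), although COX5B (-1.03) was its only called member, over all probe sets and adjusted over the list alone, and the call was lost in 6 of 28 alternatives, quantile normalization among them (adjusted p = 0.065, with 0.00496 to 0.298 over all 28). GH3 genes had 2 rises, of DAO1 (1.39) and GH3.3 (1.17, from 3000 ± 242 to 6810 ± 1070), and the fall of GH3.17 (-1.49), with 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.399). Among glutathione transferases 2 rose (GSTU25 by 4.42, GSTU22 by 3.04) and 4 fell (GSTU20 -2.59), with unchanged counts adjusted over the list alone (camera adjusted p = 0.27). The alternative chain list again had NDB4 (2.39) and NDB2 as its called members, also adjusted over the list alone (camera adjusted p = 0.0588). Of the expansin and XTH genes 3 rose, with XTH18 at 2.63 and XTH20 at 1.98, and 2 fell, with EXPA15 at -1.39, against 3 and 3 adjusted over the list alone (camera adjusted p = 0.437).

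Of the 4 lateral root genes, PGLR fell by 2.82, the transcription factors LBD29 and PUCHI fell by 1.1 and 0.64, and LBD16 rose by 1.05. Both root hair expansins fell, EXPA18 by 2.84 and EXPA7 by 2.64, as did BCAT4 (-3.57) and the 3 cell cycle genes (AUR2 -0.94, MCM7 -0.69, AUR1 -0.41). LTI30 rose by 2.44, LDH by 3.25 and GRX480 by 2.89. GR2 fell by 0.59, a call lost in 6 of 25 alternative settings, and PRXIIF (-0.38) was called adjusted over the list alone. AT2G37870 (-4.67), AT5G03350 (-4.42) and AT5G48490 (-3.91) had the largest other falls of named genes, and AT5G42830 (4.75) was among the largest rises. In total 5648 probe sets (24.8%) were called, 2643 higher and 3005 lower, 1708 of them changed at least 2-fold (989 higher, 719 lower), and 36.1% of probe sets did not overlap between the groups. Under other groupings of the 6 arrays camera called up to 5 lists, against 8 with the real groups.

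Across genes, which are not independent replicates, the antimycin A effects on the 2 media correlated at 0.802. No array is shared between these comparisons. Both use the same estimate of spread per probe set, however, which by itself raises the overlap of their calls. Both called 1204 probe sets at 2-fold or more, of which 1199 moved in the same direction. Of these 752 were higher on both media, where lists of those sizes drawn independently would share 55.6, and 447 lower on both, against 35.2. Over probe sets called on B5 the slope of the effect on NAA against that on B5 was 0.689 ± 0.0501 (jackknife SE over the 12 arrays), but over those called on NAA it was 0.850 ± 0.0509, so that the slope depended on which arrays chose the probe sets.

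**Figure D2:**
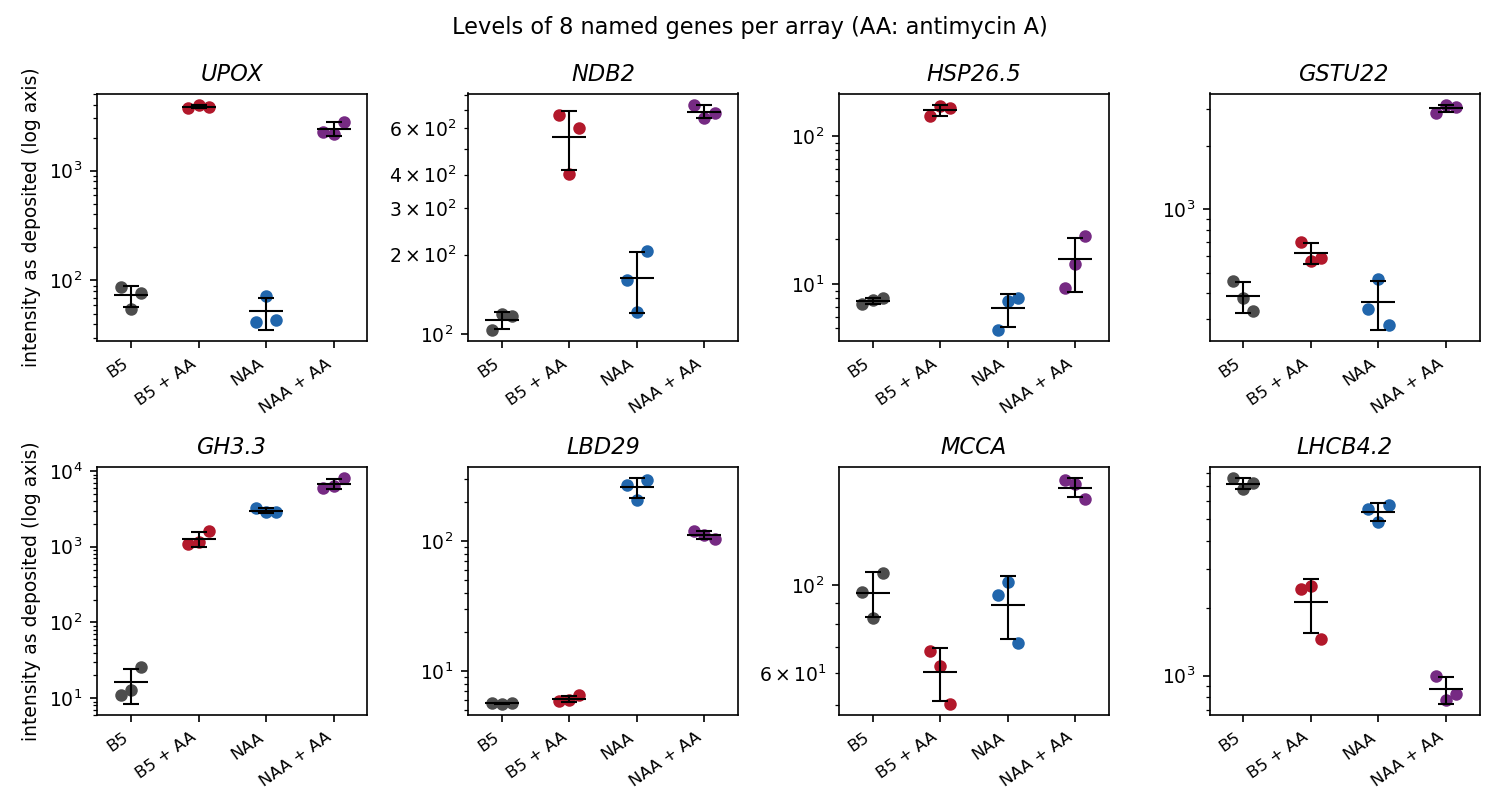
Intensity as deposited (vertical axes, log scale) of 8 named genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group (bars); AA is antimycin A. UPOX and NDB2 rose with antimycin A on both media, HSP26.5 reached 150 on B5 but 14.7 on NAA, GSTU22 reached 618 on B5 and 3020 on NAA, and LBD29 was high on NAA alone (259) and lower with antimycin A (111).

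The third comparison asked what 3 days on NAA changed in untreated seedlings. GH3 genes, whose enzymes conjugate auxin to amino acids and which auxin is known to induce, had the highest median of the lists tested: GH3.3 went from 16.4 ± 7.98 on B5 to 3000 ± 242 on NAA (SD, n = 3; log2 6.57 ± 0.20, adjusted p = 3.66e-07), and GH3.5 from 44.0 ± 7.47 to 1620 ± 334 (4.75 ± 0.15, adjusted p = 4.78e-07). LBD29, a transcription factor of lateral root initiation, went from 5.68 ± 0.05 to 259 ± 45.8 (3.65 ± 0.10, adjusted p = 2.27e-07). AT2G19970 went from 81.4 ± 14.3 to 7780 ± 848 (6.33) and PR-1-LIKE from 21.5 ± 8.16 to 2860 ± 407 (6.27). Of 7 photosynthesis genes 4 fell, a list whose camera call was lost with an estimated correlation (adjusted p = 0.396), with PSAN going from 9210 ± 390 to 4950 ± 90.9 (-0.89 ± 0.18, adjusted p = 0.00645).

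Of 6 GH3 and auxin inactivation genes 4 rose with NAA, and 4 adjusted over the list alone (median 1.41, camera adjusted p = 0.000269, and adjusted p = 0.0295 with an estimated correlation), GH3.17 by 1.82. All 4 lateral root genes rose, with PUCHI at 1.00 and LBD16 at 0.97 beside LBD29, and both root hair expansins rose, EXPA7 by 1.78 and EXPA18 by 1.56. Of 10 respiratory chain genes 4 rose, and 5 adjusted over the list alone (median 0.29, camera adjusted p = 0.00226, but adjusted p = 0.374 with an estimated correlation), among them SDH1-1 of complex II (0.54), COX6A of complex IV (0.38) and cytochrome c CYTC-1 (0.33). Of 7 photosynthesis genes 4 fell, and 5 adjusted over the list alone, with a median of -0.47. Its camera adjusted p was 0.00226, with adjusted p = 0.396 with an estimated correlation, and 0.164 after median centring of the arrays (4.61e-05 to 0.396 over its 28 alternatives). PRK fell by 0.92 and PSAE1 by 0.41.

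The remaining lists were not called without antimycin A. Of 6 Aux/IAA genes IAA29 (1.1) and IAA30 (0.35) rose, also adjusted over the list alone (camera adjusted p = 0.19). Of 10 retrograde genes AT12CYS-2, a mitochondrial protein with twin cysteine motifs, rose by 0.96 and AT3G10930 fell by 1.29, with the same count adjusted over the list alone (camera adjusted p = 0.775), and UPOX and NDB2 had values of -0.39 (adjusted p = 0.197) and 0.44 (adjusted p = 0.184). The alternative dehydrogenase NDC1 fell by 0.55, the single call in its list of 5 by either adjustment. Of the 6 heat shock genes limma called 0 by either adjustment and 0 at an unadjusted p below 0.05 (median -0.02), and UGT73B1 fell by 0.80 as the only one of 6 detoxification genes, also adjusted over the list alone. GSTU18 and GSTU20 fell by 1.48 and 0.80, against 1 rise and 2 falls of 8 adjusted over the list alone. Among expansin and XTH genes 3 rose (XTH18 1.27, XTH33 0.75) and 3 fell (EXPB1 -0.72), with 3 and 4 adjusted over the list alone. Of 5 sugar starvation genes D2HGDH fell (-0.52, lost in 7 of 25 alternative settings), and of 5 rapid stress genes WRKY6 rose (0.86) and ZAT10 fell (-1.08), with the same counts adjusted over the list alone. For these 7 lists after the retrograde list the camera adjusted p was 0.775 or above. LTI30 rose by 1.09. The cell cycle genes had values of 0.26 for AUR1 (adjusted p = 0.119) and -0.19 for MCM7 (adjusted p = 0.27), and no antioxidant, hypoxia, jasmonate, salicylic acid, glucosinolate, clock or stomatal gene measured was called by limma, although 2 of 4 antioxidant genes and 1 gene each of the jasmonate, glucosinolate and stomatal lists had an unadjusted p below 0.05 and were called adjusted over the list alone. Transcripts of the plastid genome, a set chosen after the annotation was seen, were lower too: 34 of 69 fell (median -0.68, camera adjusted p = 7.4e-14, but adjusted p = 0.559 with an estimated correlation).

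The largest falls of named genes with NAA were AT1G31690 (-2.90), AT1G66100 (-2.30), AT1G06830 (-1.95), the ERF transcription factor ORA47 (-1.84), scpl31 (-1.80) and AT2G43550 (-1.73), and EXPB2 (4.88) and AT5G52390 (4.45) were among the largest rises. In all 4637 probe sets (20.4%) were called, 2437 higher and 2200 lower, and 1075 changed at least 2-fold (538 higher, 537 lower). Groups did not overlap for 39.3% of probe sets. After median centring, which lowered the NAA arrays by 0.09 on the log2 scale, the split was 2136 higher and 9866 lower (18% higher, against 52.6% as deposited). Under other groupings of the 6 arrays camera called up to 2 lists, against 3 with the real groups.

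The fourth comparison asked what NAA changed among seedlings that had received antimycin A. GH3.3 was at 1280 ± 284 on B5 and 6810 ± 1070 on NAA (SD, n = 3; log2 2.41 ± 0.20, adjusted p = 5.97e-05) and GH3.5 at 164 ± 14.8 and 2190 ± 161 (3.62 ± 0.15, adjusted p = 1.71e-06). Of 6 heat shock genes 4 were lower with NAA, HSP26.5 by far the most, from 150 ± 12.8 to 14.7 ± 5.87 (-2.45 ± 0.12, adjusted p = 3.81e-06), and ROF2 from 306 ± 48.6 to 117 ± 8.55 (-1.27 ± 0.10, adjusted p = 5.44e-05). MCCA and IVD were higher with NAA, from 60.3 ± 9.10 to 176 ± 9.73 (1.34) and from 67.7 ± 3.91 to 177 ± 16.5 (1.2). COR15A, a chloroplast protein of cold and dehydration responses, went from 255 ± 118 to 2440 ± 840 (3.22 ± 0.47, adjusted p = 0.00122).

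Of 6 GH3 and auxin inactivation genes 4 were called higher, and 4 adjusted over the list alone, with GH3.17 at 1.39 (median 1.11, camera adjusted p = 0.000341, and adjusted p = 0.0244 with an estimated correlation). Of 6 heat shock genes 4 were lower, and 5 adjusted over the list alone, with HSP23.5 at -1.10 (median -1.18, camera adjusted p = 0.000341, and adjusted p = 0.0346 with an estimated correlation). Of 5 sugar starvation genes 3 were higher, by either adjustment (median 0.77, camera adjusted p = 0.000385, and adjusted p = 0.0244 with an estimated correlation). Of 7 photosynthesis genes 4 were lower, while 1 rose and 5 fell adjusted over the list alone. Their median was -1.0, with PSAN at -1.61, LHCB4.2 at -1.25 and PSAE1 at -1.14. The camera adjusted p of this list was 0.00611, with adjusted p = 0.413 with an estimated correlation, and 0.19 after median centring (0.000327 to 0.413 over its 28 alternatives).

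Of 10 retrograde genes 1 was higher and 5 lower with NAA, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.212). UPOX was lower (2400 ± 351 against 3830 ± 147, log2 -0.68, adjusted p = 0.0291, a call lost in 6 of 25 alternative settings), AT2G04070 had -1.12 and DTX3 -0.62, the last with its call lost in 9 of 25 alternative settings, whereas AT12CYS-2 was higher (1.89) and NDB2 had 0.34 (adjusted p = 0.296). Among Aux/IAA genes IAA29 (2.23) and IAA30 (1.80) were higher and IAA18 lower (-0.34), also adjusted over the list alone (camera adjusted p = 0.125). Glutathione transferases had 3 higher, GSTU22 by 2.26 and GSTU25 by 1.39, and 2 lower, GSTU20 by -1.50, the same adjusted over the list alone (camera adjusted p = 0.437). Of 6 detoxification genes 3 were lower, by either adjustment, with UGT73C1 at -1.59 and UGT76E12 at -0.90 (camera adjusted p = 0.086). Of 10 respiratory chain genes 2 were higher, COX6A (0.39) and QCR7 (0.28), and 2 lower, CYTC-2 (-0.55) and COX5B (-0.34), with 4 and 2 adjusted over the list alone (camera adjusted p = 0.086). Of 9 expansin and XTH genes 2 were higher, XTH19 (1.58) and XTH20 (0.87), and 2 lower, XTH16 (-0.97) among them, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.437). No alternative chain or rapid stress gene was called by either adjustment (camera adjusted p = 0.746 and 0.842), and 1 of 5 and 2 of 5 had an unadjusted p below 0.05. Of 69 plastid genome transcripts 37 were lower (median -0.72, camera adjusted p = 7.96e-12, but adjusted p = 0.611 with an estimated correlation).

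In the lists too small for a test, LBD16 (2.22), LBD29 (2.52) and PUCHI (0.36) were higher with NAA, AUR1 (0.55) and AUR2 (0.52) were higher, and the 3 dehydration genes were all higher (LTI30 2.28, COR47 0.75). EXPA18 was higher by 0.89 and GI by 0.39, while BCAT4 was lower (-2.10). GR1 was higher by 0.42, a call lost in 7 of 25 alternative settings, 5 of them the removal of a single array. The defensin PDF1.2A was higher by 1.4, a call lost in 8 of 24 settings, with 1 array of NAA with antimycin A at 115 and the others at 32.5 and 42.4. No hypoxia, salicylic acid or stomatal gene measured was called, and 1 hypoxia gene had an unadjusted p below 0.05. Of the other named genes AT2G19970 (6.34), AT5G54370 (4.14), AT5G64100 (4.1), PR-1-LIKE (3.97), AT3G19200 (3.83) and AT5G01870 (3.73) had the largest rises, and AT3G21080 (-3.33), AT4G30450 (-2.64), AT5G59680 (-2.41), AT2G37870 (-2.41) and AT4G03450 (-2.39) the largest falls beside HSP26.5. In all 4994 probe sets (22%) were called, 2779 higher and 2215 lower, and 1149 changed at least 2-fold (682 higher, 467 lower), with 40.7% not overlapping. After median centring, which lowered the NAA arrays by 0.117 on the log2 scale, 2381 were higher and 10984 lower (18% higher, against 55.6% as deposited), and the values above are relative to the deposited scale. Under other groupings of the 6 arrays camera called up to 3 lists, against 4 with the real groups.

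**Figure D3:**
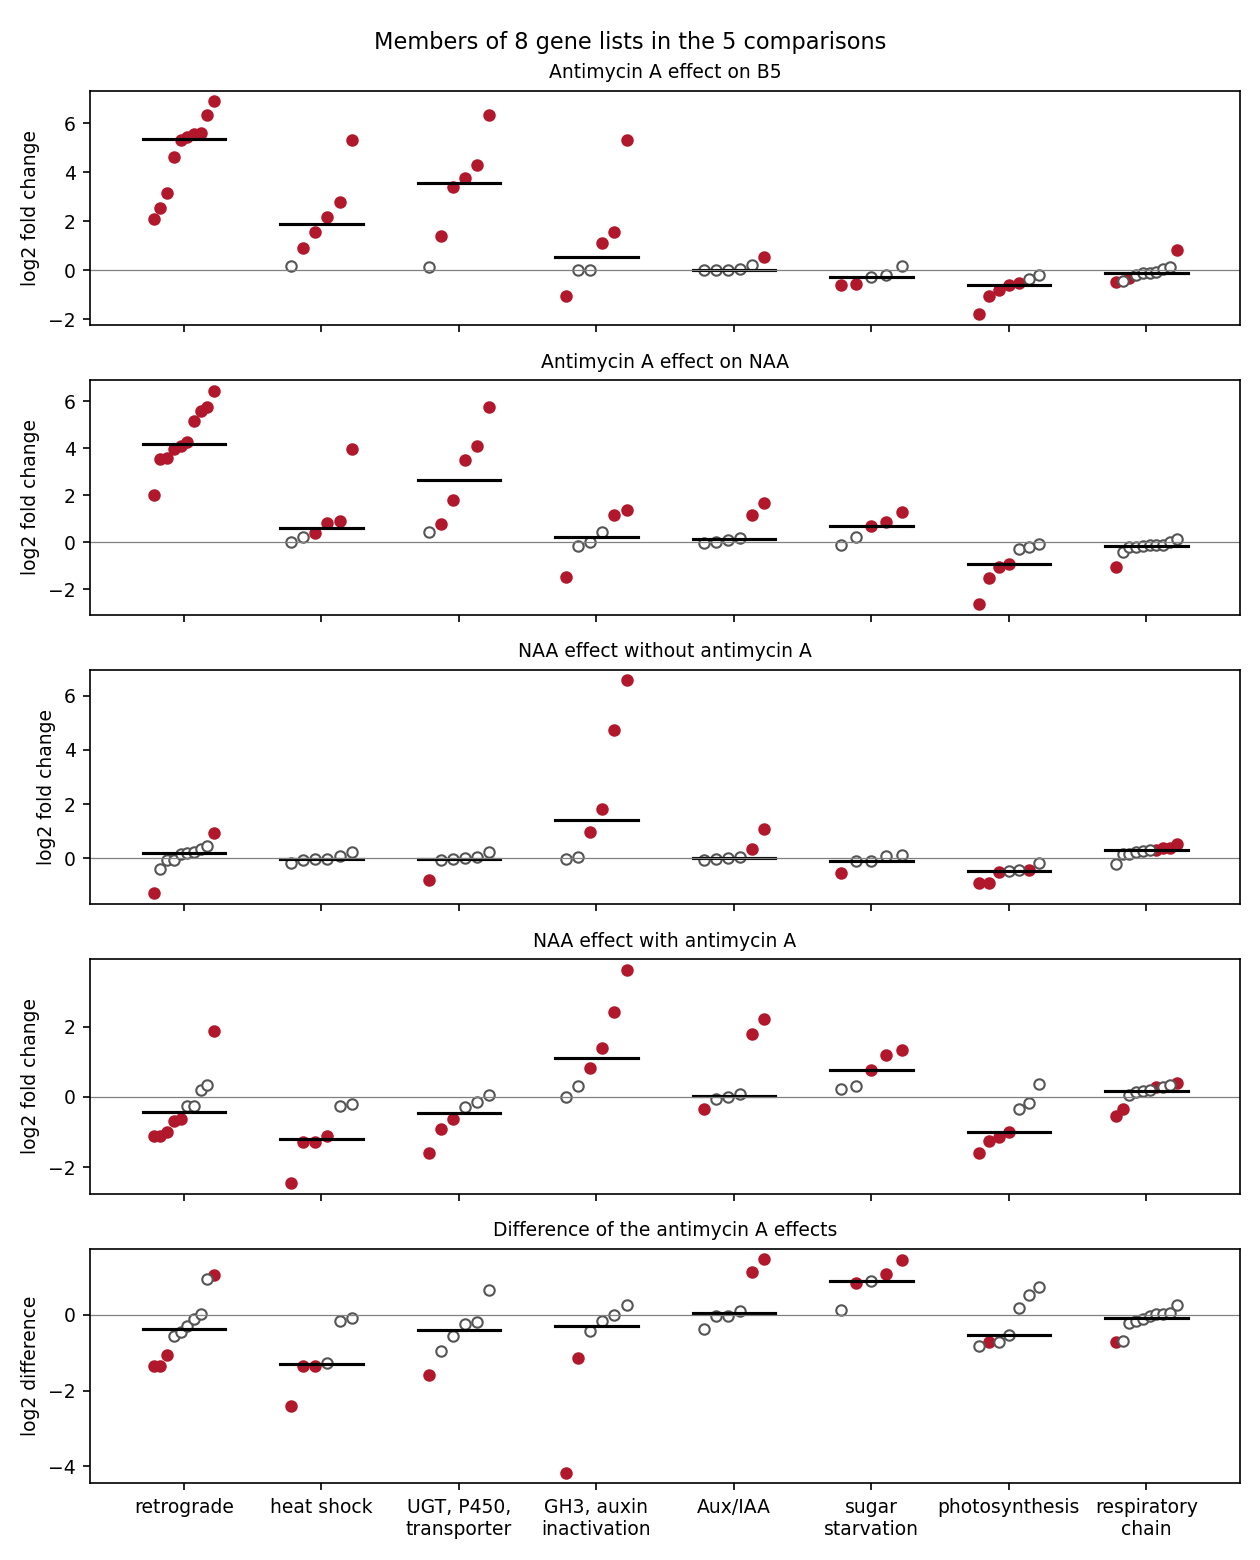
Log2 fold change (vertical axes; log2 difference in the lowest panel) of each measured member of 8 fixed gene lists in the 5 comparisons, with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at the list's median. The 10 retrograde genes rose in both antimycin A panels (medians 5.38 and 4.19), heat shock genes had a median of 1.88 on B5 and 0.62 on NAA, and GH3 genes were highest in the NAA panels (medians 1.41 and 1.11); the vertical scales differ between panels.

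The fifth comparison, the difference of the antimycin A effects, asked whether NAA altered the response to antimycin A and is the test of every contrast between the media drawn here. A positive difference is a larger rise or a smaller fall on NAA, or a change of direction, and a negative one the reverse. Higher and lower in this comparison refer to that sign. GH3.3 had the clearest change among the lists, a rise of 5.33 on B5 and of 1.17 on NAA (difference -4.16 ± 0.28 SE, adjusted p = 0.000121), from baselines of 16.4 and 3000. HSP26.5 rose by 2.81 on B5 and 0.41 on NAA (-2.40 ± 0.17, adjusted p = 0.000166). GSTU22 did the opposite, with rises of 0.66 and 3.04 (2.38 ± 0.25, adjusted p = 0.000914), and MCCA fell by 0.55 on B5 but rose by 0.88 on NAA (1.43 ± 0.19, adjusted p = 0.00222). The responses of NDB2 and UPOX did not differ by more than the spread between arrays (-0.10 ± 0.29, adjusted p = 0.981, and -0.29 ± 0.26, adjusted p = 0.673).

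Of 6 heat shock genes 3 responded less with NAA, and 4 adjusted over the list alone (median difference -1.31, camera adjusted p = 8.8e-05, and adjusted p = 0.0316 with an estimated correlation), with ROF2 at -1.36 and HSP23.5 at -1.35. Of 5 sugar starvation genes 3 had a positive difference, and 4 adjusted over the list alone (median 0.88, camera adjusted p = 8.83e-05, and adjusted p = 0.0267 with an estimated correlation), with IVD at 1.08 and D2HGDH at 0.83, the last with its call lost in 9 of 24 alternative settings. These were the called lists, yet 46 of 100 rearrangements of the arrays' deviations also called 2 lists or more. Of 10 retrograde genes 3 responded less (HSP23.5, AT5G43450 at -1.34, a call lost in 9 of 24 alternative settings, and AT2G04070 at -1.07) and AT3G10930 more (1.04), with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.172). GH3.5 also rose less on the log2 scale (-1.14), which with GH3.3 gave 2 of 6 in its list by either adjustment (camera adjusted p = 0.0619). Before antimycin A, GH3.5 read 35.46 to 49.3 on B5 and 1248.78 to 1901.21 on NAA. IAA30 (1.46) and IAA29 (1.13) responded more, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.185).

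Glutathione transferases had 2 positive differences, against 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0714). GSTU22 rose more on NAA, while GSTU18 fell on both media and fell less on NAA (0.89, with the call lost in 12 of 24 alternative settings). UGT73C1 was lower (-1.60), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.185). Of 9 expansin and XTH genes 3 were higher and 2 lower, against 4 and 2 adjusted over the list alone (camera adjusted p = 0.383), with XTH18 at -2.01 and XTH33 at -1.06. EXPA8 had 2.22, a smaller fall on NAA than on B5, with its call lost in 14 of 24 settings. PSAE1 (-0.72) was the called photosynthesis gene of 7, against 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.383). COX5B (-0.73) was that of 10 respiratory chain genes, against 2 lower adjusted over the list alone (camera adjusted p = 0.208). No alternative chain or rapid stress gene was called by either adjustment (camera adjusted p = 0.895 and 0.873), with 0 and 1 at an unadjusted p below 0.05. In the smaller lists the difference was positive for LBD16 (1.25) and LTI30 (1.19). It was negative for PGLR (-1.58), EXPA7 (-1.58) and BCAT4 (-1.41), which fell more on NAA. EXPA7 read 17.62 to 38.24 on B5 before antimycin A and 4.68 to 5.34 with it, so a further fall there could hardly be seen. LBD29 (-1.13) and PUCHI (-0.64) had negative differences too. On the B5 arrays they read 5.63 to 6.54 and 8.06 to 10.92, so a fall could hardly be seen there. No cell cycle, hypoxia, antioxidant, jasmonate, salicylic acid, clock or stomatal gene measured was called, and 1 gene each of the hypoxia, jasmonate and clock lists had an unadjusted p below 0.05. Adjusted over the list alone, PDF1.2A (1.54), GI (0.45) and COR15A (2.27) were called higher and EXPA18 (-0.68) lower.

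The largest negative differences of named genes outside GH3.3 were EXPB2 (-4.27), AT3G22060 (-4.22), AT2G37870 (-3.96), AT3G21080 (-3.32) and AT3G61930 (-2.80), and the largest positive ones AT3G15450 (3.2), AT3G15630 (3.00), AT5G19120 (2.63), AT4G33666 (2.48), AT5G62360 (2.47) and AT1G31690 (2.45). EXPB2 read 4.96 to 8.1 and AT3G61930 5.96 to 10.87 on the B5 arrays, so a fall could hardly be seen there. AT3G15450 fell from 1460 ± 295 to 453 ± 71.7 on B5 and went from 592 ± 44.8 to 1740 ± 156 on NAA. In all 2168 probe sets (9.53%) had a called difference, 1170 positive and 998 negative, 792 of them of at least 2-fold (398 positive, 394 negative). Among the 1073 probe sets whose antimycin A effect averaged over the media was a called rise of at least 2-fold, 279 had a called smaller rise with NAA and 79 a called larger one. Among the 775 with an average fall, 138 had a called smaller fall with NAA and 79 a larger one. Across all probe sets the antimycin A effect and the NAA effect, each averaged over the other treatment so that they share no error, had a Pearson correlation of -0.0338 ± 0.0619 (jackknife SE over the arrays) and a Spearman correlation of -0.0637.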

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

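Among the tests weighed here, those on falls and larger rises, on organelle genomes, nuclear photosynthesis genes and the median of all genes were chosen only after the result was seen. The counts of smaller and larger rises and falls were themselves defined after the values were seen, while the test of levels reached and the rearrangements of arrays were set before their own outcome was known.

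NAA changed the response to antimycin A, by the test of the difference of the antimycin A effects, for 2168 probe sets, 792 of them at least 2-fold. Of 100 rearrangements of the arrays' deviations from an additive model 1, the real one, gave counts as large, and the highest others gave 16 and 2. The deviations still hold the difference itself, which widens the spread of each rearrangement and lowers its counts. The rank of 1 in 100 thus speaks against chance for both counts without excluding it. Chance cannot be excluded for the number of called lists either: 46 of the 100 gave 2 or more, and the highest other gave 6. The difference left in the deviations may enter these list counts too. The lists called with the real arrangement were heat shock genes (median difference -1.31) and sugar starvation genes (0.881). With 3 arrays against 3 there are 10 splits, too few for a share under 0.05 in the 4 single comparisons. The real counts of called probe sets and highest others were 7504 and 1 for antimycin A on B5, 5648 and 1 on NAA, 4637 and 2 for NAA without and 4994 and 3 with antimycin A. At 2-fold or more they were 2392, 1708, 1075 and 1149, with 0 in the others, and for lists 5 and 6 (4 of the 10 splits gave 5 or more), 8 and 5, 3 and 2, and 4 and 3. The other splits mix the groups unequally, which keeps part of the effect and widens the spread. Their counts are therefore not those of arrays without an effect.

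Named genes whose response differed between media, in the direction of NAA minus B5, included GH3.3 (-4.16), GH3.5 (-1.14), IAA30 (1.46), IAA29 (1.13), LBD16 (1.25), LBD29 (-1.13) and PUCHI (-0.64) among auxin and lateral root genes. Heat shock and retrograde genes with a smaller response were HSP26.5 (-2.40), ROF2 (-1.36), HSP23.5 (-1.35), AT5G43450 (-1.34, its call lost in 9 of 24 alternatives) and AT2G04070 (-1.07). Cell wall genes were EXPB2 (-4.27), XTH18 (-2.01), EXPA7 (-1.58), XTH33 (-1.06) and EXPA8 (2.22, lost in 14 of 24). Metabolic genes were MCCA (1.43), IVD (1.08), D2HGDH (0.827, lost in 9 of 24), BCAT4 (-1.41), PSAE1 (-0.725) and COX5B (-0.728), and detoxification genes GSTU22 (2.38), GSTU18 (0.887, lost in 12 of 24) and UGT73C1 (-1.60). LTI30 had 1.19. The others were AT3G22060 (-4.22), AT2G37870 (-3.96), AT3G21080 (-3.32), AT3G61930 (-2.80), AT3G15450 (3.2), AT3G15630 (3.00), AT5G19120 (2.63), AT4G33666 (2.48), AT5G62360 (2.47) and AT1G31690 (2.45). EXPB2, AT3G61930, LBD29 and PUCHI read 4.96 to 10.92 on every B5 array, so a fall with antimycin A could hardly be seen there. Their negative differences reflect falls on NAA alone. AT1G31690 began at 16.24 to 30.54 on NAA, which left it little room to fall. EXPA7 read 17.62 to 38.24 on B5 before antimycin A and 4.68 to 5.34 with it, so a further fall there could hardly be seen. GH3.3 and GH3.5 began at 10.97 to 25.57 and 35.46 to 49.3 on B5, against 2840.05 to 3280.95 and 1248.78 to 1901.21 on NAA.

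Of probe sets that rose at least 2-fold with antimycin A on average, 279 rose less with NAA and 79 rose more, and of those that fell 138 fell less and 79 fell more. None of 100 rearrangements apart from the real one gave as many in any of these counts (highest others 0, 2, 0 and 1). The limit given above for rearrangements applies here too. Levels near a maximum on NAA are argued against as the whole cause, since 80.3% of the smaller rises ended at a called lower level with NAA and antimycin A than with antimycin A alone, although 34.8% began at a called higher level with NAA before antimycin A, as that explanation needs, so it stays open for part of them. The smaller rises were chosen by a difference that contains this end level, which by itself raises the 80.3% and weakens the argument. A shift of whole arrays would deepen falls, but the median difference among falls was 0.248 (jackknife SE 0.107). A single common weakening, by the same factor for every gene, leaves no room for 79 larger rises, where 17.9 false calls would be allowed. A general weakening of unequal size is not excluded, since 72.88% of the rises and 63.87% of the falls were smaller with NAA, called or not. A response of seedlings on auxin that differs in part of the genes stays open as a biological explanation and was not tested.

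Transcripts of the plastid genome were lower with NAA, the mean score by -0.659 (SE 0.0569, exact permutation p = 0.005, the smallest the rearrangements can give, adjusted p = 0.015 over 9 scores). Less copying of RNA without a poly(A) tail during labelling would lower mitochondrial genome transcripts alike, but the mitochondrial minus plastid NAA effect was 0.66 (SE 0.0596, exact permutation p = 0.005) and 25S ribosomal RNA was 0.359 higher. A smaller share of green tissue is consistent with the mean of the nuclear photosynthesis genes, which was also lower with NAA (-0.639, SE 0.088, exact permutation p = 0.005). A lower transcript level per green cell would look the same, and tissue was not measured.

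The 25S ribosomal RNA control, which no comparison used, was higher with antimycin A by 0.80 on average (SE 0.0449, exact permutation p = 0.005, adjusted p = 0.009), on all 6 treated arrays against the untreated arrays of the same medium. Mitochondrial genome transcripts were also higher, by 0.44 (SE 0.0375, exact permutation p = 0.005). A shift of whole arrays, such as a loss of messenger RNA hidden by normalization, stays open. The values carry marks of normalization between arrays, which could by itself keep the median over all probe sets (0.00811) near 0. Array medians were not held fully equal, though, at 33.72 to 36.2 on B5 and 38.81 to 39.73 on NAA. More copying of RNA without a poly(A) tail would raise plastid transcripts too. The mitochondrial minus plastid antimycin A effect was 0.337 (SE 0.0596, exact permutation p = 0.005, adjusted p = 0.009) and the plastid effect 0.103 (exact permutation p = 0.09), which speak against it, but the first passes the bound of 0.3 set for that test by less than its SE and ribosomal RNA rose as the explanation needs, so it may be part of the cause, and neither it nor such a shift can be told apart from a biological rise of mitochondrial transcripts.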

How the results depend on the processing

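The counts of smaller and larger rises and falls were added after the data were seen; the alternatives were planned. No called value of a named gene, list or family reversed in any alternative, but the balance of calls with NAA did: without antimycin A 2437 higher and 2200 lower became 2349 and 2597 after quantile normalization and 2136 and 9866 after median centring, and with it 2779 and 2215 became 2537 and 2822, and 2381 and 10984. Of 239 called values of named genes, 205 were called with the same sign in every alternative run; beside a gene, lost calls are given from 6 alternatives up. Of 167 uncalled named genes, lists and families, 68 were called in at least 1.

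Median centring gave 12000 called probe sets for NAA without and 13360 for NAA with antimycin A (4637 and 4994 as deposited), mostly lower by less than 2-fold; the NAA arrays have the higher medians, which this setting removes. With a single probe set per gene, which leaves 13355, called probe sets were 3853, 2692, 2317, 2468 and 1043 over the 5 comparisons in the order of the report, and 1200, 808, 576, 545 and 391 at 2-fold or more; smaller and larger rises were 135 and 42, smaller and larger falls 75 and 34. A pseudocount of 64, which shrinks folds of dim probe sets, gave 1490, 1037, 544, 616 and 384 at 2-fold or more, 50 larger rises, and 67 smaller and 46 larger falls; a pseudocount of 1 gave 213 and 129 such falls. Called lists were 3, 3, 1, 1 and 0 without the dimmer 50% of probe sets, where 6 and not 12 lists could be tested. With an estimated correlation 2 (B5), 1 (NAA) and 1 (NAA without antimycin A) were called, and fry, which does not compare a list with other genes, called 11 on B5 and 5 for the difference; the cause was not tested further.

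Leaving out an array in turn gave 2 to 6 lists for the difference, 4 without B5 array 3 and 6 without array 2 of B5 with antimycin A. A group left with 2 arrays used the spread of all groups. The ranges were 6421 to 7597, 4483 to 5703, 3400 to 4671, 3934 to 5034 and 1578 to 2325 called probe sets, 0.664 to 0.724 for the slope and -0.0641 to 0.00885 for the correlation of average effects, whose sign was therefore not settled. Whether arrays of the same replicate number share more than the number is not settled. Of 18 same-numbered pairs of arrays 5 had deviations correlated above 0.1 (range -0.103 to 0.35), and 6 of 12 arrays had their best partner under their own number. The number 2 arrays of B5 with antimycin A, NAA and NAA with antimycin A correlated with each other at 0.35, 0.264 and 0.314. A replicate block gave 7537, 5683, 4627, 5012 and 2159 called probe sets, 7145, 5258, 4234, 4578 and 1837 of them shared with the fit without it, and changed no called list, while 3 named gene values and 1 family lost their call. Results planned for AOX1A were not run. Signal over background limits dim genes: at intensities near 5 to 10, as for HSP26.5 before treatment, the pseudocount sets the fold.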

Other observations

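The gene families, organelle genomes and ratios of control probe sets described here, and their tests, were chosen only after the annotation or the values were seen, while the overlap of both effects was planned. With antimycin A on B5, WRKY transcription factors rose (5 of 6, median log2 1.14, camera adjusted p = 0.0117, but adjusted p = 0.363 with an estimated correlation), as did calmodulin-like CML genes (4 of 7, median 0.75, camera adjusted p = 0.02, but adjusted p = 0.38 with an estimated correlation) and U-box PUB genes (5 of 9, median 0.23, camera adjusted p = 0.0376, but adjusted p = 0.38 with an estimated correlation). PUB genes lost the call in 12 of 27 alternative settings. Alpha-expansins fell (6 of 10, median -1.21, camera adjusted p = 0.015, but adjusted p = 0.363 with an estimated correlation), and so did aldehyde dehydrogenases (6 of 8, with 1 rise, median -0.53, camera adjusted p = 0.0117, but adjusted p = 0.522 with an estimated correlation) and beta-tubulins (4 of 5, median -0.52, camera adjusted p = 0.0267, but adjusted p = 0.522 with an estimated correlation). Of 29 serine carboxypeptidase-like genes 11 fell, 2 rose and 16 were not called, with a median of -0.015 (camera adjusted p = 0.02, but adjusted p = 0.522 with an estimated correlation). Of 16 mitochondrial genome transcripts 7 rose on B5 and 5 on NAA, with medians of 0.32 and 0.28 (camera adjusted p = 0.0142 and 0.0147, but adjusted p = 0.522 and 0.408 with an estimated correlation). On NAA, WRKY (4 of 6) and CML genes (3 of 7) rose with antimycin A as well (camera adjusted p = 0.0147 and 0.0282, but both adjusted p = 0.408 with an estimated correlation).

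With NAA in the absence of antimycin A, CRR (chlororespiratory reduction) genes of the chloroplast fell (4 of 5, median -0.86, camera adjusted p = 0.0209, but adjusted p = 0.559 with an estimated correlation and 0.157 after median centring, within 0.00175 to 0.559 over its 26 alternatives). Among seedlings with antimycin A, autophagy ATG genes were higher with NAA (4 of 8, median 0.56, camera adjusted p = 0.00885, but adjusted p = 0.611 with an estimated correlation), as were aldehyde dehydrogenases (5 of 8, with 1 lower, median 0.40, camera adjusted p = 0.0209, but adjusted p = 0.745 with an estimated correlation). In the difference of the antimycin A effects camera called 0 of the 45 families and genomes, with 4 at an unadjusted p below 0.05, and fry called 2. The 3' to 5' ratios of the GAPDH, actin and ubiquitin control probe sets, a gauge of RNA integrity, had average antimycin A effects of 0.0447, 0.303 and 0.318 on the log2 scale (exact permutation p = 0.86, 0.53 and 0.09) and NAA effects of 0.164, 0.318 and 0.0522 (exact permutation p = 0.5, 0.51 and 0.765). Their SE were 0.237, 0.473 and 0.154, so equal RNA integrity is not shown. Group means of the log2 actin ratio were 3.71 to 4.37, and the ubiquitin ratio went from -0.13 to 0.403 with antimycin A on B5.

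Probe sets called for both average effects were more than independent lists would share in each combination of directions. Of them 874 were higher with both treatments, against 637 for independent lists, and 1315 lower with both, against 690.7. Another 775 were higher with antimycin A and lower with NAA, against 541.9, and 1451 the reverse, against 811.9. Both effects are tested with the same estimate of spread per probe set, so a probe set of small spread is more easily called for both. Independent lists are therefore not a chance level here, and the excess does not show that both treatments act on the same genes.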
